A study of Mus musculus with 6 samples.

How the data were processed

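Total RNA of dorsal cortex from mouse embryos at E14.5 was labelled with biotin by an Illumina TotalPrep amplification and read on Illumina bead arrays, per the labels' protocols. The 6 samples were grouped by the genotype in their titles into 3 of Tbr2 fl/fl;Foxg1::Cre (mutant) and 3 of Tbr2 +/+;Foxg1::Cre (control), and the replicate numbers are those of the titles. The deposited table holds 1 intensity per probe and array, on a linear scale, and the submitters' processing notes name GenomeStudio 2010.3. Whether the authors subtracted background or normalized the values is not given in the sources used here. In the table the lowest intensity per array lies between 83.4 and 96.5, so values were treated as not background-subtracted, and array quartiles differ by up to 0.723 on the log2 scale, so they were treated as not normalized. The table holds no detection calls, so no probe could be marked as below background.

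The design rule fixed before the data were examined adds an offset only where the 0.5th percentile of all intensities lies below 16; it lay at 103.4, so the offset was 0. Intensities were converted to log2 and quantile-normalized between arrays. Because background was left in the values, the log2 difference of a dim probe understates its change: the mean log2 value over arrays was 6.80 at the 0.5th percentile of probes and 7.58 at the 50th. Probe names come from the platform annotation: of 45281 probes, 34885 had 1 gene symbol, 18 had several and were not named, and 10378 were not listed and are unnamed here. Of the probes with 1 symbol, 34807 had an Entrez identifier in the RefSeq gene table of GRCm38.p6, which changed 0 symbols and was used only for names and for which genes neighbour each other. Of 19057 genes, 9172 had more than 1 probe, and the probe with the highest mean over the 6 arrays stood for the gene. The 11864 genes whose probe lay in the upper 50% of all probes were tested. Of the 136 called genes, 62 had another probe in the upper 50%, and for 57 of these every such probe had the same sign.

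Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, Benjamini-Hochberg over the genes tested, threshold 0.05). Fold changes are mutant minus control on the log2 scale, and the median standard error was 0.101. Both Eomes probes were also compared with an exact two-sided permutation test. Before the data were examined, 32 gene lists were written from textbook markers of the embryonic cortex, of other cells that dissected tissue can hold, and of tissue handling. They hold 443 genes, of which 339 were tested, and the 31 lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. Named genes were fixed by a rule set at the same time: all probes of Eomes, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, and up to 4 members of each list by smallest p. Clone names without information were skipped among the ranked genes, which left out 0 rises and 1 fall; 6 of the called genes have such names. Members were named for lists that passed or held a called gene, a restriction made after the values were seen.

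The limma fit and the list test were tested on simulated values for the comparison of mutant and control. Normalization, the choice of probes and the brightness filter were not simulated. With 200 of 11864 genes changed in 20 simulations, the fit found 62% of genes changed 1.5-fold and 89.4% of those changed 2-fold, with 3.93% false calls. A shifted list was found in all 20 simulations and an unshifted list in 0, and simulations without changed genes gave 0 calls. The simulated noise was independent between genes, whereas members of the measured lists had estimated correlations of up to 0.647 (mitosis). The simulations therefore cannot check the list calls made at the preset correlation. Their rates of false calls among genes likewise hold only for independent noise. Alternatives set before the data were examined were median centring, other offsets and floors, other filters on dim probes, the mean of a gene's probes or every probe alone, a variance trend, array weights, the replicate number as a block, no shrinkage, other thresholds and leaving out each array. Added after the data were seen were normexp background correction, the Xist level as a covariate and a test without the chromosome that carries Eomes. No deposited column was left out.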

Results

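RNA from the dorsal cortex of mouse embryos (C57BL/6, E14.5) was measured on Illumina bead arrays, in which each probe's brightness reports the abundance of a transcript. The 6 arrays fell into 2 groups of 3 that both carried Foxg1::Cre, a Cre recombinase driven from a gene active in the forebrain. The arrays labelled mutant held tissue with both copies of Tbr2 flanked by loxP sites (Tbr2 fl/fl), and the arrays labelled control held tissue with intact Tbr2 (Tbr2 +/+). Tbr2, whose gene symbol is Eomes, is a T-box transcription factor made in the intermediate progenitors of the cortex, which arise from radial glia and divide to give projection neurons. Each array gave values for 45281 probes, with a median intensity of 180.1, 193.9 and 167.9 on mutant replicates 1, 2 and 3 and of 175.5, 213.3 and 227 on control replicates 1, 2 and 3. After normalization, pairs of arrays within a group correlated across the tested genes at 0.9904 to 0.9952 and pairs between groups at 0.9855 to 0.9937. The first principal component held 38.6% of the variance and separated the groups, with mutant replicate 2 (score −19.38) farther from the controls (4.7 to 13.14) than mutant replicates 1 (−4.69) and 3 (−5.97). The labels do not say whether replicates came from separate embryos or litters, so p-values measure the spread between these samples, and the number of arrays limits the precision. All 6 samples were on 1 chip with each group in neighbouring positions, so chip position and genotype cannot be told apart.

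The single comparison of the design asked which transcripts differ in the cortex when Tbr2 is removed. Both probes of Eomes gave a clear signal on every array and pointed in opposite directions. The probe matched to the Eomes RefSeq transcript read 11.14 ± 0.25 log2 on the mutant arrays and 11.75 ± 0.23 on the control arrays (mean ± SD, n = 3 each), 1.53-fold lower (log2 difference −0.61, SE 0.153, limma adjusted p = 0.144 over all probes tested). The brighter probe, matched to a cDNA clone of Eomes, read 11.84 ± 0.24 against 11.21 ± 0.14, 1.55-fold higher (log2 difference 0.63, SE 0.131). Its limma adjusted p was 0.0839 over all probes tested and 0.07 over the genes tested. For each probe the groups did not overlap, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. Neither difference passed the threshold, and the mean of both probes differed by 0.01. Because the brighter probe stands for a gene, the Eomes value turned to −0.59, −0.75 and −0.50 without mutant replicate 1, 2 or 3, when the RefSeq probe became the brighter. Where either probe lies relative to the deleted part is not given in the sources used here, so Eomes does not check the genotype labels, and directions below are those of the arrays labelled mutant.

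Of 11864 genes tested, 136 differed between the arrays labelled mutant and control at an adjusted p under 0.05, 55 higher and 81 lower in the mutant. Among them 50 differed at least 2-fold, 19 higher and 31 lower. With background left in the values, the largest measured rise was in Ebf3, an early B-cell factor transcription factor, from 11.51 ± 0.03 to 13.85 ± 0.16 log2 (5.07-fold, log2 fold change 2.34, SE 0.0978, adjusted p = 1.87e-05). Its relatives Ebf2 (3.03-fold) and Ebf1 (2.44-fold) rose as well, and every probe of these genes among the brighter 50% of the array pointed the same way. Uncx, a homeobox gene, rose 4.50-fold (log2 fold change 2.17, SE 0.196, adjusted p = 0.000859) from a control mean of 7.39 ± 0.23, below the median probe (7.58), so its fold is understated. With normexp background correction, chosen after the data were seen, the order turned (log2 fold changes of 2.58 for Uncx and 2.36 for Ebf3). The control means of Gbx2 (7.24) and Cdhr1 (7.34) also lay below the median probe. The other genes among the 10 largest rises were Lmcd1 (2.98-fold), Chodl (2.97-fold), the thalamic homeobox gene Gbx2 (2.96-fold), Adcyap1, which encodes the neuropeptide PACAP (2.86-fold), Gng8 (2.73-fold), Cdhr1 (2.69-fold) and the bHLH gene Olig3 (2.55-fold). Adjusted p for these 7 genes lay between 0.000155 and 0.000761.

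The largest measured fall was that of Wdr82, 5.63-fold lower on 1 of its 4 probes (log2 fold change −2.49, SE 0.151, adjusted p = 0.000155), while its 3 other probes, all dimmer, differed by 0.02 to 0.13 in the other direction. Ly6g6e fell 4.93-fold to a mutant mean of 7.40 ± 0.12, below the median probe, so its fold is understated, and normexp correction turned the order (log2 fold changes of −2.71 for Ly6g6e and −2.65 for Wdr82). Cemip, a hyaluronan-degrading protein, fell 4.28-fold. Atp2c1, a Golgi calcium pump, was 2.84-fold lower on 1 probe (log2 fold change −1.50) and differed by 0.12 in the other direction on its second. Gpr176 (2.86-fold), Ndrg1 (2.57-fold), Slc17a7 (2.57-fold), the axon guidance receptor Robo2 (2.50-fold), Mpped1 (2.46-fold) and the neuronal calcium sensor Hpca (2.42-fold) completed the 10 largest falls, with adjusted p from 0.000155 to 0.0184. Slc17a7 encodes the vesicular glutamate transporter VGLUT1. Ndrg1 lost the call without mutant replicate 3, control replicate 1 or control replicate 2 (adjusted p up to 0.081).

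All 136 called genes had groups that did not overlap, as did 17.2% of all genes tested, where chance gives 10%. The count was 65 without mutant replicate 3 and 80 without control replicate 1, and 6 in a limma fit with no shrinkage of the variances, where Ebf3 and Olig3 were the only named genes to keep their calls. Centring each array on its median gave 29 higher and 76 lower. Averaging the probes of a gene moved the log2 fold changes of Uncx to 1.19, Ebf1 to 0.72, Chodl to 0.50, Wdr82 to −0.56, Atp2c1 to −0.69, Cemip to −0.75 and Robo2 to −0.50.

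**Figure D1:**
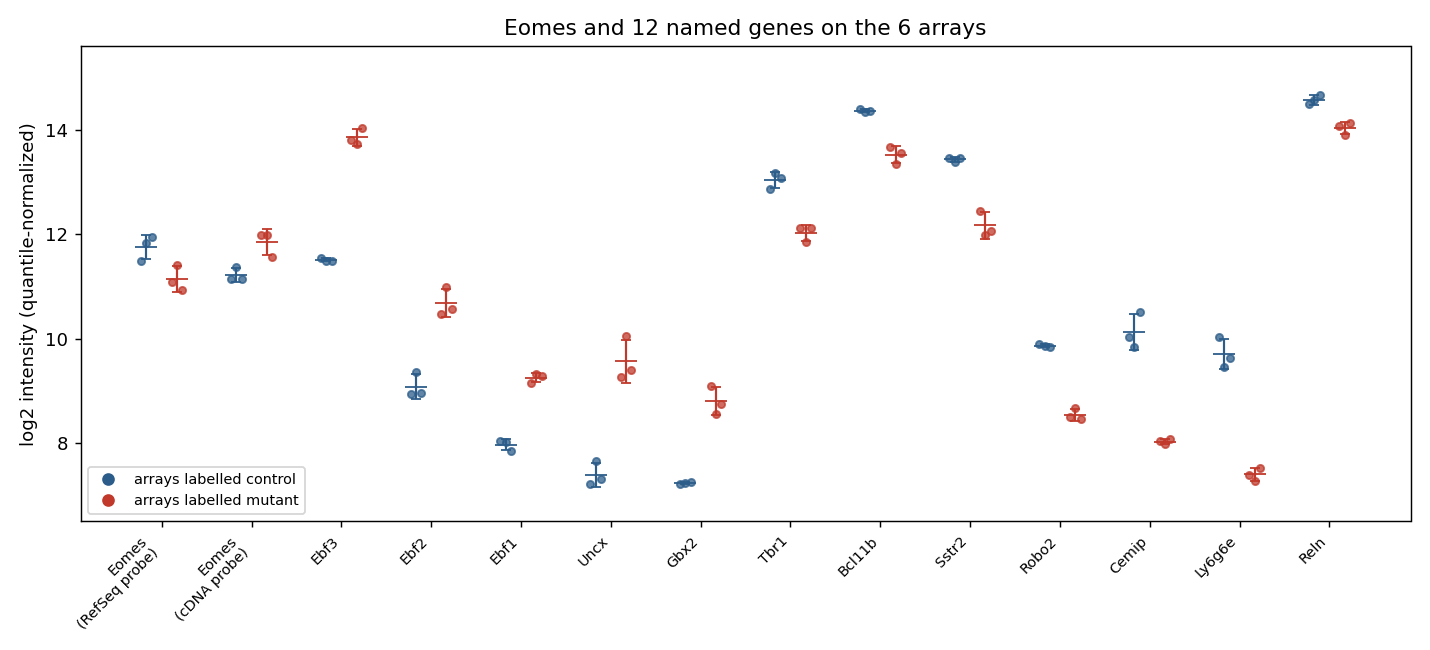
Normalized log2 intensity (vertical axis) of both Eomes probes and of named genes on each of the 6 arrays, with arrays labelled control in blue and arrays labelled mutant in red. Dots are single arrays and bars give the mean ± SD (n = 3); the Eomes probes differ by −0.61 and 0.63, and Ebf3 lies at 11.49 to 11.54 on the control arrays and 13.73 to 14.03 on the mutant arrays.

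In the list of intermediate progenitors, the cells that make Tbr2, the genes that passed moved in opposite directions. Of 16 measured members, Sstr2, a somatostatin receptor, fell from 13.43 ± 0.04 to 12.16 ± 0.26 log2 (2.41-fold, adjusted p = 0.00128), Mfap4 rose 1.66-fold (adjusted p = 0.0168), and 14 did not pass. Over all genes tested 136 of 11864 passed, so calls were more frequent in this list. Adjusted over the list alone, 4 rose and 3 fell. Neurod4 (log2 fold change −0.42, adjusted p = 0.083) and Insm1 (0.36, adjusted p = 0.0872) were among those that missed the threshold over all genes. The list was not shifted in 1 direction as a whole (camera adjusted p = 0.674), and its median (0.10) and mean (−0.01) differed in sign. It passed fry's mixed test, which takes changes in either direction (adjusted p = 0.00142). Mfap4 lost its call without mutant replicate 2 or 3 or control replicate 1 (adjusted p up to 0.102), and with median centring.

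Of 14 measured genes of deep-layer neurons, the first projection neurons to be made, 4 fell in the mutant, both over all genes and adjusted over the list alone: Tbr1 and Bcl11b (CTIP2), transcription factors of layer 6 and layer 5 neurons, fell 2.02-fold and 1.79-fold (log2 fold changes −1.01, SE 0.114, and −0.84, SE 0.0986; adjusted p = 0.00284 and 0.00347), Nfe2l3 fell 1.76-fold and Wnt7b 1.97-fold. The list as a set ranked lower at the preset correlation, with a median of −0.28 (camera adjusted p = 0.000309, and adjusted p = 0.485 with an estimated correlation). The median was −0.12 without mutant replicate 2, with the call kept (camera adjusted p = 0.000803). Fezf2, which specifies subcortical projection neurons and was chosen after its value was seen, had a log2 fold change of 0.07 (adjusted p = 0.841). Wnt7b (adjusted p = 0.045) lost its call when any array but mutant replicate 2 was left out (up to 0.19), with the upper 30% of probes, with every probe tested alone and with a variance trend and robust fit. Bcl11b and Nfe2l3 did not pass when the probes of a gene were averaged.

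Of 15 genes of synapses and neuronal maturation 1 fell, and the list as a set ranked lower than other genes at the preset correlation, with a median of −0.19 (camera adjusted p = 0.00602, and adjusted p = 0.485 with an estimated correlation). The gene that fell was Slc17a7 (log2 fold change −1.36, SE 0.182, adjusted p = 0.00715), and the other 14 did not pass; adjusted over the list alone, 3 fell. Camk2b (−0.74, adjusted p = 0.134), Syt1 (−0.65, adjusted p = 0.153) and Grin2b (−0.59, adjusted p = 0.489) were among these 14. Grin2b passed without control replicate 3 (log2 fold change −0.96, limma adjusted p = 0.0224). In the axon guidance and adhesion list, Robo2 fell (log2 fold change −1.32, SE 0.0896, adjusted p = 0.000155) and 18 of 19 members did not pass, with 2 falls adjusted over the list alone. Epha3 (−1.03, adjusted p = 0.136), Cntn1 (−0.26, adjusted p = 0.335) and Sema6d (−0.35, adjusted p = 0.338) did not pass over all genes. That list had a median of −0.10 (camera adjusted p = 0.0116, and adjusted p = 0.485 with an estimated correlation). Both lists lost the call without mutant replicate 2 or control replicate 2 (camera adjusted p up to 0.0761 and 0.235), and axon guidance also when probes were averaged. The synapse median was −0.11, −0.11 and −0.09 without mutant replicate 2, control replicate 1 or control replicate 2 and −0.12 with array weights, and the axon guidance median was −0.15, −0.03 and −0.19 without mutant replicate 1, control replicate 1 or control replicate 3 and −0.16 with the upper 30% of probes or the Xist level as a covariate.

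None of 7 subplate genes passed over all genes, and 2 rose adjusted over the list alone, St18 (log2 fold change 0.62, adjusted p = 0.0506 over all genes) and Nxph4 (0.95, adjusted p = 0.0564). Nr4a2 (0.30) and Lpar1 (0.21) had adjusted p of 0.531 and 0.642. As a list they ranked higher than other genes at camera's preset correlation, with a median of 0.22 (camera adjusted p = 0.0116, and adjusted p = 0.431 with an estimated correlation), the call was lost without mutant replicate 1 (0.0604), and the median was 0.14 without control replicate 3. The immature projection neuron list (median −0.13, 15 members, camera adjusted p = 0.072) and the upper-layer list (median −0.01, 12 members, camera adjusted p = 0.848) held no called gene and did not pass, with 1 rise and 2 falls in the first and none in the second adjusted over the list alone. The immature neuron list passed, as lower, with median centring (0.0374), the upper 30% of probes (0.00798), the Xist covariate (0.036) and without mutant replicate 1 (0.0045), mutant replicate 3 (0.0207) or control replicate 3 (0.00468), and the upper-layer list without control replicate 3 (0.0423). The immature neuron median was −0.22 without control replicate 3, −0.07 without mutant replicate 2 and −0.04 with averaged probes.

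Among 9 Cajal-Retzius genes, markers of the early neurons of the cortical surface, Ebf3 and Ebf2 rose, Reln fell and 6 did not pass, with the same counts adjusted over the list alone. Reln, the secreted signal of these cells, read 14.57 ± 0.09 log2 in the control and 14.03 ± 0.12 in the mutant (1.45-fold lower, log2 fold change −0.54, adjusted p = 0.0323). Its call was lost whichever array was left out (adjusted p up to 0.11), with median centring and when probes were averaged; a second probe near background differed by 0.04 in the other direction. Lhx5 had a log2 fold change of 0.32 (adjusted p = 0.364). The list did not pass (camera adjusted p = 0.252, direction up), although its median was −0.07 and its mean 0.37, and it passed with median centring (0.0262) and when probes were averaged (0.0126).

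Markers of the ventral telencephalon and its interneurons, which migrate into the cortex, ranked lower as a list at the preset correlation, with a median of −0.51 over 11 members (camera adjusted p = 0.00102, and adjusted p = 0.485 with an estimated correlation). No member fell over all genes, Ebf1 rose (log2 fold change 1.29, SE 0.093, adjusted p = 0.000221), and 8 fell and 1 rose adjusted over the list alone. Dlx1 (−0.88, adjusted p = 0.15), Dlx2 (−0.55, adjusted p = 0.17) and Gad2 (−0.55, adjusted p = 0.175), genes of GABAergic neurons, were lowest on mutant replicate 2. Dlx1 read 8.07 there against 9.05 and 9.02 on the other mutant arrays and 9.57 to 9.61 on the controls. Without mutant replicate 2 the fall of Dlx1 was smaller and passed over all genes (log2 fold change −0.56, limma adjusted p = 0.0354). The list's call was lost with the upper 30% of probes (median −0.87, camera adjusted p = 0.254). The median was −0.14 with no filter on dim probes and −0.34 without mutant replicate 2. The call was kept in both (camera adjusted p = 0.0126 and 0.000387).

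The 2 lists for tissue that borders the dorsal cortex ranked higher than other genes at the preset correlation, with 1 called gene between them. The 6 thalamic and diencephalic genes had a median of 0.32 (camera adjusted p = 0.00162, and adjusted p = 0.431 with an estimated correlation). Of these Gbx2 rose, 5 did not pass, and 3 rose adjusted over the list alone. Gbx2 read 7.24 ± 0.01 log2 on the control arrays, below the median probe (7.58), and 8.80 ± 0.27 on the mutant arrays, so its fold is understated. The thalamic median was 0.06 with no filter on dim probes, with the call kept (camera adjusted p = 0.00321). That call was also kept whichever array was left out (camera adjusted p up to 0.0112). Irx3 (0.25), Lhx9 (0.38) and Tcf7l2 (0.38) had adjusted p of 0.277, 0.282 and 0.418. The 15 genes of the cortical hem, choroid plexus and hippocampal anlage had a median of 0.22 (camera adjusted p = 0.000491, and adjusted p = 0.485 with an estimated correlation). None passed over all genes and 3 rose adjusted over the list alone. The smallest p-values there were those of Rspo1 (0.38, adjusted p = 0.0651), Otx2 (0.57, adjusted p = 0.143), Prox1 (0.42, adjusted p = 0.169) and Rspo2 (0.39, adjusted p = 0.331). Ttr, an abundant transcript of choroid plexus chosen after its values were seen, read 11.41 on mutant replicate 2 against 7.06 to 8.04 on the other 5 arrays, and the list kept its call whichever array was left out (camera adjusted p up to 0.00885). Its median was 0.14 with median centring. Areal genes did not pass as lists. The list written as caudal (8 members, median 0.04, mean −0.05, camera adjusted p = 0.899, direction down) held Cdh8. Cdh8 fell 2.09-fold (adjusted p = 0.00277) to a mean below the median probe (7.34). It lost its call, though not its direction, without mutant replicate 3 (adjusted p = 0.0721). Whether Cdh8 marks caudal cortex was not tested, so its fall is not read as a change of caudal identity. Adjusted over that list alone, 1 rose and 1 fell. Efna5 (0.57, adjusted p = 0.134), Epha7 (−0.32, adjusted p = 0.38) and Tenm3 (0.17, adjusted p = 0.565) did not pass. The rostral list (8 members, median −0.03, camera adjusted p = 0.848) held no called gene by either adjustment.

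The lists of dividing cells, Notch signalling, radial glia and hypoxia ranked higher at the preset correlation, and no member of them passed over all genes. The 11 mitosis genes were all above 0 with a median of 0.21 (camera adjusted p = 0.00602, and adjusted p = 0.539 with an estimated correlation). Among them Aurka (0.39, adjusted p = 0.263), Cdc20 (0.24, adjusted p = 0.355), Birc5 (0.29, adjusted p = 0.418) and Aurkb (0.24, adjusted p = 0.523) had the smallest p-values. Of 17 DNA replication genes 16 were above 0, with a median of 0.15 (camera adjusted p = 0.00808, and adjusted p = 0.576 with an estimated correlation). Mcm5 (0.23), E2f1 (0.24) and Gins2 (0.21) each had adjusted p = 0.527, and Ccne2 went down (−0.32, adjusted p = 0.342). The 8 Notch signalling genes were all above 0 with a median of 0.20 (camera adjusted p = 0.00808, and adjusted p = 0.485 with an estimated correlation), among them Nrarp (0.38, adjusted p = 0.215), Dll4 (0.21, adjusted p = 0.467), Notch3 (0.35, adjusted p = 0.509) and Dll1 (0.24, adjusted p = 0.634). The 20 apical radial glia genes had a median of 0.11 (camera adjusted p = 0.0464, and adjusted p = 0.485 with an estimated correlation). The Notch effector Hes5 (0.46, adjusted p = 0.0559) was the only one of these members to rise adjusted over the list alone, and Mt3 (0.31), Hes1 (0.20) and Prom1 (0.17) had adjusted p of 0.527, 0.527 and 0.549. The 9 hypoxia and glycolysis genes had a median of 0.18 (camera adjusted p = 0.0116, and adjusted p = 0.431 with an estimated correlation). Ankrd37 (0.27), Aldoa (0.23), Vegfa (0.18) and Pdk1 (0.20) had adjusted p from 0.382 to 0.545. Without mutant replicate 2 the mitosis, DNA replication, Notch and radial glia calls were lost, and without control replicate 1 the DNA replication, Notch, radial glia and hypoxia calls (camera adjusted p up to 0.235, 0.288, 0.0924, 0.18 and 0.0564 for mitosis, DNA replication, Notch, radial glia and hypoxia). The radial glia call was also lost without mutant replicate 3 or control replicate 2, with normexp background correction and with the upper 30% of probes. With the replicate number as a block it was lost too (camera adjusted p = 0.06). Without mutant replicate 2 the medians of mitosis, DNA replication and Notch genes were 0.12, 0.10 and 0.11, and with median centring those of mitosis, DNA replication and hypoxia genes were 0.13, 0.08 and 0.09. With no filter on dim probes the mitosis and hypoxia medians were both 0.11, with averaged probes the hypoxia median was 0.10, with the Xist covariate the DNA replication median was 0.23, and without control replicate 3 the radial glia median was 0.18.

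Of the other cell types that dissected cortex can hold, erythroid genes held 1 called gene among 9 members, and the list as a set ranked lower at the preset correlation, with a median of −0.07 (camera adjusted p = 0.0171, and adjusted p = 0.485 with an estimated correlation). Alas2, of heme synthesis, fell 1.71-fold (adjusted p = 0.0434), 8 did not pass, and 2 fell adjusted over the list alone. Slc4a1 (−0.48), Fech (−0.24) and the haemoglobin gene Hba-a1 (−0.16) had adjusted p of 0.174, 0.518 and 0.541. The erythroid call was lost without control replicate 2 (0.282), with median centring, when probes were averaged, with array weights and with the Xist level as a covariate (median −0.02). The erythroid median was −0.16 with the upper 30% of probes and −0.11, −0.11 and −0.17 without mutant replicate 1, mutant replicate 2 or control replicate 1. Alas2 lost its call when any array but control replicate 1 was left out (up to 0.178), with median centring, with the upper 30% of probes, when probes were averaged and when every probe was tested alone. Among 6 genes of meninges and fibroblasts Cxcl12, a chemokine, fell 1.45-fold (adjusted p = 0.0264), with 1 fall adjusted over the list alone as well. The 2 other probes of Cxcl12 among the brighter 50% lay at −1.05 and −0.89, and its call was lost with median centring and when any array but control replicate 2 was left out (up to 0.135). Dcn (0.26), Foxc1 (−0.16) and Nid1 (0.11) did not pass (adjusted p of 0.503, 0.642 and 0.723), nor did the list (median 0.08, mean −0.03, camera adjusted p = 0.848, direction down). The lists of endothelium and pericytes (12 members, median −0.02, camera adjusted p = 0.674) and of microglia and macrophages (11 members, median −0.09, camera adjusted p = 0.0831) held no called gene by either adjustment, and neither did the oligodendrocyte list, which had 3 measured members and was not tested. The microglia list passed, as lower, with averaged probes (0.0433), array weights (0.047), the Xist covariate (0.0445) and without mutant replicate 1 (0.0336) or control replicate 2 (0.0357).

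The remaining lists did not pass, and held no called gene by either adjustment. These were Wnt/beta-catenin targets (median 0.21, camera adjusted p = 0.217), interferon response (−0.10, 0.115), ribosomal proteins (0.08, 0.363), the nuclear-encoded respiratory chain (−0.03, 0.674), heat shock and unfolded protein response (−0.01, 0.864), immediate early genes (−0.06, 0.848), p53 targets and apoptosis (−0.01, 0.909, direction up) and chromatin regulators (−0.04, 0.932, direction up). Ribosomal proteins passed with median centring (0.00346) and Wnt/beta-catenin targets with averaged probes (0.0471). The sex-linked list did not pass either (median −0.53, camera adjusted p = 0.403). Of its members, chosen after their values were seen, Xist, made from the inactive X chromosome, read 13.31, 13.45 and 12.97 log2 on mutant replicates 1 and 3 and control replicate 1, and 7.56 to 7.62 on the other 3 arrays, where the Y-linked Eif2s3y was high (10.93 to 11.35). In all, 13 of 31 lists passed by camera, 8 higher and 5 lower. None passed with an estimated correlation or by fry, which tests whether members move one way on balance, and 14 passed by fry's mixed test, which takes changes in either direction.

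**Figure D2:**
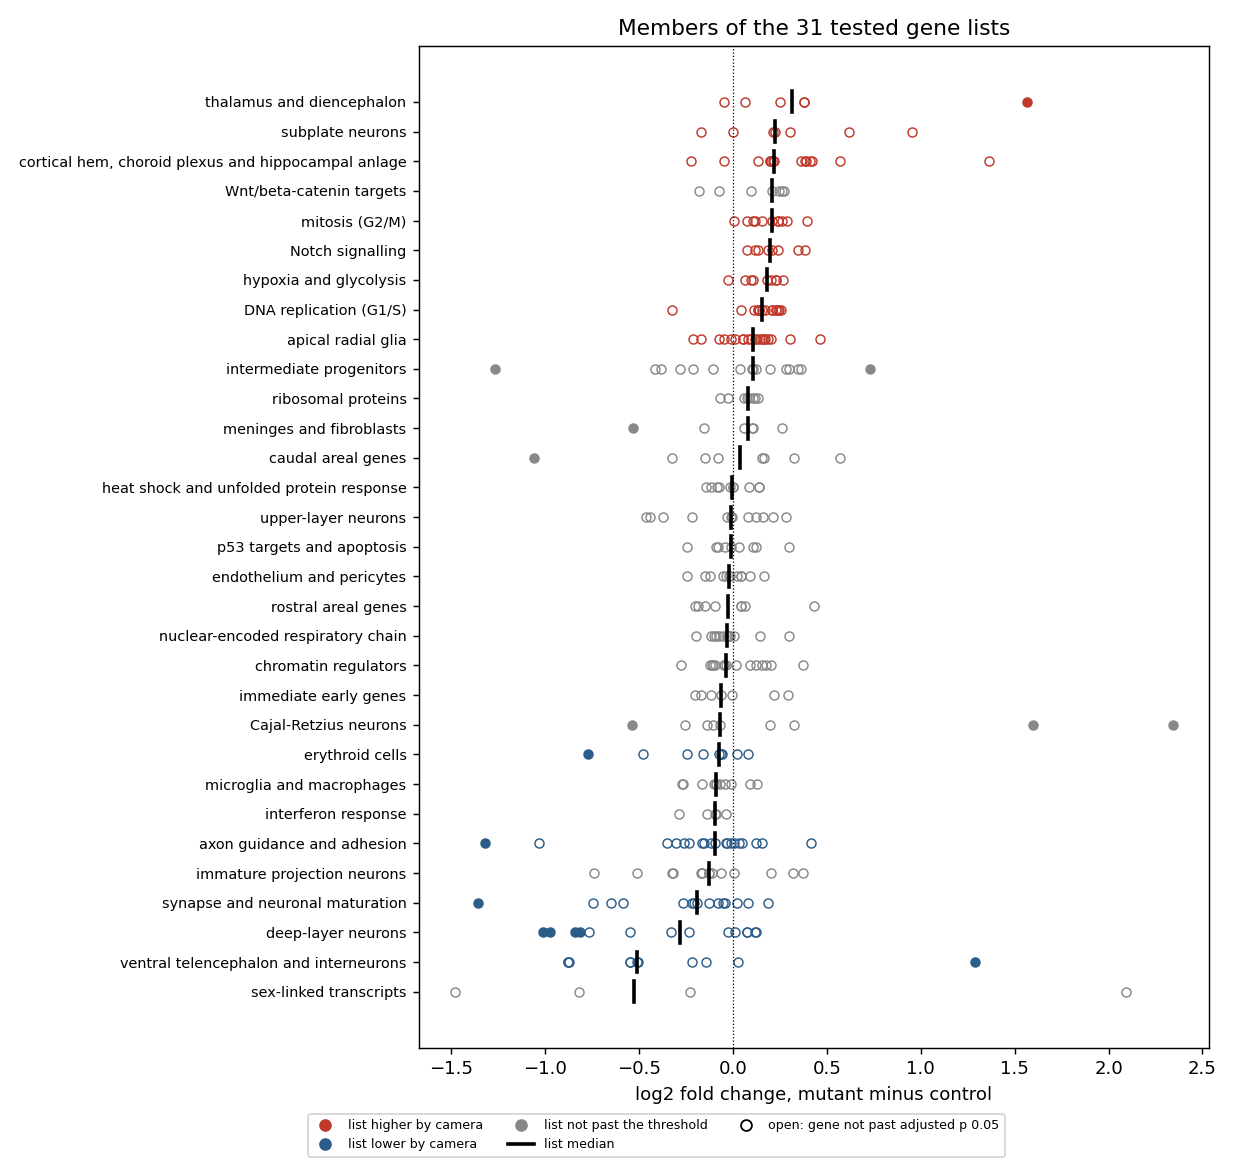
Log2 fold change, mutant minus control (horizontal axis), of each measured member of the 31 tested gene lists (vertical axis, ordered by the list median, black bar). Filled dots are genes past adjusted p 0.05, and colour gives the list's camera result; 4 of 14 deep-layer members fell, and Ebf2 and Ebf3 stand far above the other Cajal-Retzius genes.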

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

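Normexp correction, the Xist covariate and the fit without the Eomes chromosome were chosen after the data were seen. Against 136 genes (55 higher, 81 lower), normexp gave 139 (132 shared), and the alternatives not given here stayed within 1.5 times the count. The Xist covariate gave 312 (94 higher, 218 lower; all 136 shared), adjusted p under 0.1 gave 216 (89 higher, 127 lower), and a fit without shrinkage gave 6 (3 higher, 3 lower; 5 shared). Median centring gave 29 higher. The replicate number as a block gave 259 (89 higher, 170 lower; all 136 shared). The deviations of same-numbered arrays from their group means correlated at 0.358, 0.297 and 0.078. Mutant replicates 1 and 2 correlated best with the control of the same number, and mutant replicate 3 with control replicate 1. Xist was high on mutant replicate 3 and control replicate 1 and low on control replicate 3. These values cannot decide whether the numbers pair the samples, so the block was kept as an alternative only. Of the gene lists past the threshold, the block ended the call of apical radial glia (camera adjusted p = 0.06). Leaving out 1 array gave 65 to 104 genes (26 to 49 higher, 39 to 58 lower) and 7 to 15 gene lists, the 7 without mutant replicate 2. Of 31 named genes past the threshold, 22 stayed past it in every alternative in which they were tested but the fit without shrinkage; Uncx, Gbx2, Cdhr1 and Olig3 were not among the upper 30% of probes, and Wdr82 and Atp2c1 lie on the Eomes chromosome. Of 52 not past it, 14 passed in at least 1 alternative. The offset and floor alternatives changed no value, since the offset is 0 in each.

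The brighter Eomes probe passed with a variance trend and robust fit (0.6285, adjusted p = 0.0454), the block (0.6285, 0.0229) and the Xist covariate (0.6893, 0.0347). Over all alternatives the limma adjusted p of the Eomes value ran from 0.0229 to 0.991, the highest with both probes averaged. Leaving out 1 array gave −0.7513 to 0.7105, the sign turning because another probe became the brighter; the RefSeq probe stayed between −0.7513 and −0.5017. Hba-a1 turned to 0.01688 with median centring; the cause was not tested.

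Of gene lists, 0 passed with an estimated correlation and 0 by fry. Lists not past the threshold turned their camera direction as follows, with the list median and the cause not tested: rostral areal 0.04256 (mean of probes); caudal areal 0.1531 (no filter, upper 30%, mean of probes) and 0.06585 (array weights); p53 targets −0.03804 and respiratory chain −0.07111 (median centring); meninges 0.06505 (no filter) and 0.1005 (upper 30%); immediate early 0.02492 (upper 30%); sex-linked 0.0327 (Xist covariate). Leaving out 1 array gave medians of −0.1356 to 0.06938 (upper-layer), −0.1531 to 0.0174 (rostral), −0.1144 to 0.1558 (caudal), −0.02055 to 0.03038 (p53), −0.03421 to 0.023 (chromatin), −0.0336 to 0.1583 (meninges), −0.06678 to 0.02902 (endothelium), −0.112 to −0.01325 (immediate early), −0.05898 to 0.06392 (heat shock) and −0.07263 to 0.01917 (respiratory chain). Signal near background limits the dimmest genes, whose differences are understated.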

Other observations

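The tests below on genes near Eomes, on the Ebf genes and on sex-linked transcripts were chosen only after the result was seen; the counts of other splits were planned. Genes in this and the next paragraph lie outside the naming rule and were chosen after their values were seen. Other called genes that fell include the kinase Camk4 (2.40-fold, adjusted p = 0.00127), the nitric oxide synthase Nos1 (2.36-fold, adjusted p = 0.00181), the glutamate receptor subunit Gria3 (2.29-fold, adjusted p = 0.00115), the neurotensin receptor Ntsr1 (2.24-fold, adjusted p = 0.00715) and the potassium channel Kcnh3 (2.14-fold, adjusted p = 0.00403). The receptor tyrosine kinase Kit fell 1.84-fold (adjusted p = 0.0144). For each of these genes all 3 mutant arrays lay below all 3 control arrays.

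Other called genes that rose include the collagen gene Col9a2 (2.49-fold, adjusted p = 0.000698), the retinoic acid binding protein gene Crabp2 (2.46-fold, adjusted p = 0.00127), the nicotinic receptor subunit Chrna3 (2.28-fold, adjusted p = 0.00464), the nuclear receptor Esrrg (2.29-fold, adjusted p = 0.00115) and Lamp5 (2.11-fold, adjusted p = 0.00242). The zinc finger gene Zfp423, whose protein binds EBF proteins, rose 2.03-fold (adjusted p = 0.00405). Ccnd1 (cyclin D1, 1.54-fold, adjusted p = 0.0198) and Gadd45a (1.75-fold, adjusted p = 0.00755) rose too. Th, which encodes tyrosine hydroxylase, rose 1.60-fold from 7.28 ± 0.05 log2, a level near background (adjusted p = 0.0256). Of 3764 probes without a gene name here in the brighter 50%, 12 passed, 3 higher and 9 lower.

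Ebf1, Ebf2 and Ebf3 rose together by 1.29 to 2.34 log2, and 2 hypotheses were tested. More Cajal-Retzius neurons in the mutant tissue would raise Reln if its level per cell were unchanged. Reln instead lay at −0.54 (SE 0.0957), and its call was lost when any array was left out. Its mutant arrays read 13.9 to 14.12 and its control arrays 14.48 to 14.67. The 7 list members other than Ebf2 and Ebf3 had a median of −0.10 (MAD 0.23, range −0.54 to 0.32). They did not rise as a set. The level per cell was not measured, so these values cannot decide whether cell number changed. Thalamic tissue left on the mutant cortices may contribute: the 5 thalamic genes other than Gbx2 had a median of 0.25 (MAD 0.19, range −0.05 to 0.38), although none passed by itself and all lay far below the Ebf changes. That median covers only genes past the brightness filter. With no filter on dim probes the median of the thalamic list, Gbx2 included, was 0.06 instead of 0.32, with the call kept (camera adjusted p = 0.00321). The members added there lie on dim probes, whose changes are understated, so this explanation stays open. Loss of Tbr2 acting on these genes in cortical cells was not tested.

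Of genes within 200 protein-coding genes of Eomes on its chromosome, 6 of 176 tested were lower in the mutant against 75 of 11677 elsewhere (odds ratio 5.46, 95% confidence interval 1.92 to 12.7, Fisher's exact test p = 0.00127), and 0 were higher. These were Csrnp1, Tmem158, Camkv, Wdr82, Pik3r4 and Atp2c1, which lay 22, 69, 137, 191, 196 and 197 genes from Eomes. Wdr82, Pik3r4 and Atp2c1 thus lay near the edge of the window. Of the genes named, Wdr82 and Atp2c1 fell on 1 probe while their other probes did not. DNA of another mouse strain carried along with the floxed allele could change how probes bind and is a candidate explanation. However, the intervals hold 1 at 50 and 100 genes (odds ratios 2.52 and 2.95) and on the whole chromosome (1.81, interval 0.75 to 3.78). At 300 genes the interval does not hold 1 (4.6, interval 1.77 to 10.1). Of 451 overlapping windows, the Eomes chromosome included, 9 held at least 6 lower genes, and the most on another chromosome was also 6. These windows were compared by count alone, without the number of genes tested in each. An effect of Tbr2 loss without regard to position cannot be told apart from DNA of another strain by these values, since the result depends on the window. Without the genes of that chromosome, 125 genes passed, all among the 136.

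Xist was high on 2 mutant arrays and 1 control array, so the groups differ in the sex makeup of their samples. With the Xist level as a covariate, 100% of the 136 called genes stayed past the threshold. All 136 had groups that did not overlap, whereas high Xist cut across the groups and Xist itself was not called. The outcome with the covariate was thus largely set by the selection of the genes, and it is not independent evidence about sex. Of the called genes 4 are X-linked. The X-linked share of all tested genes is not given here, so no conclusion is drawn from that count.

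The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 136 genes, 1 of the 10 with as many, and the highest other split 4, the one that follows Xist. It called 13 gene lists, again 1 of the 10, and the highest other split 11.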
